A study of Mus musculus with 6 samples.

How the data were processed

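Gene expression was measured on 6 arrays in bone marrow cells of the LSK phenotype, meaning cells without mature lineage markers that carry the Sca-1 and Kit surface proteins, the gate that holds blood stem cells and multipotent progenitors. The mice carried a tamoxifen-inducible Cre recombinase under the promoter of Cdh5, the gene of the endothelial adhesion protein VE-cadherin, together with a YFP reporter at the Rosa26 locus. Per the labels, tamoxifen was given on days 1, 2 and 3 after birth and the cells were collected at postnatal day 27, which is 26 days after the first induction. Femurs and tibias were flushed, the marrow was digested with collagenase for 30 min at 37 °C, and LSK cells were sorted into 3 YFP-positive and 3 YFP-negative samples. A cell is YFP-positive if it, or a cell it descends from, had active Cre. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical in part.

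Per the labels' protocols, 500 pg of total RNA per sample was amplified with the Ovation Pico V2 system, and 3.6 µg of the product was fragmented and labelled with biotin. All RNA was extracted at the same time. The submitters' processing notes name Partek, with no version given. The background correction, the summarisation of probes and the normalization are not given in the sources used here. The deposited table holds log2 expression values, 1 column per array, for 41345 probes. That the scale is logarithmic, and that its base is 2, was read from the values, which run from 1.53 to 13.7. The medians of the 6 arrays lay between 3.62 and 3.68, which shows arrays on nearly one scale. No detection calls were used, so a level near the lower end of an array cannot be told from background, and a fold against such a level can understate the change. The number of arrays limits the precision.

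The annotation of the array's probes listed 25335 probes. Of these, 23521 had 1 gene symbol and 1814 had several. The other 16010 probes in the table were unnamed here. The gene identifiers of the named probes were compared with a RefSeq gene table of assembly GRCm38.p6. That changed 0 symbols, and the identifiers of 193 probes were not in that table. Each gene was represented by its probe with the highest mean over all 6 arrays, which gave 22180 genes. 1082 genes had several probes. Ly6a and Ddx3y had no probe listed, and the globin genes Hba and Hbb only probes with several symbols, so they were not analysed here. No coordinates are given because, apart from that RefSeq table, the sources used here name no genome build. All 6 columns of the table were used.

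Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the log2 values with the population as the only term, two-sided, with Benjamini-Hochberg adjustment over all 22180 genes at a threshold of 0.05. Differences are YFP-positive minus YFP-negative on the log2 scale. Group values are given as mean ± SD of 3 arrays, and differences with the moderated standard error (SE). A looser count took an unadjusted p under 0.05 with at least a 1.5-fold difference. The genes whose 95% interval of the difference lay between -1 and 1 were counted as well. Similarity of arrays was measured as 1 minus Pearson's correlation over the 22180 genes, and the difference between and within populations was compared over all 10 splits of the arrays into 3 and 3 by an exact permutation test, one-sided, whose smallest possible p is 0.1.

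Before the data were examined, 32 gene lists were fixed from general knowledge, covering blood stem and progenitor programs, endothelium, other cell types that the gate could hold, cell cycle, metabolism, stress and signalling. 30 of them were tested with camera, which asks whether the genes of a list shifted relative to all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 30 lists. The lists of sort gate and sex-linked genes were only described. The adjusted p with an estimated correlation is given beside each list that passed, and fry served as another alternative. Lists share some members. 4 more lists, of leukocyte, sinusoidal, arterial and fatty acid handling genes, were written after the main comparison was seen.

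Most genes named in the text were chosen by a rule fixed at the same time. It takes the 12 genes with the largest difference in each direction past the threshold, without predicted genes, receptors of smell and small RNAs. It adds 7 gate genes, up to 4 genes of smallest p from each list past its test and up to 2 from each other list, and a few fixed stem cell, endothelial, proliferation and sex-linked genes. 1 gate gene and 1 sex-linked gene had no value. Some further members of lists, such as Ptprc, Sox17, Sult1a1, Esam, Adgrg1, Mllt3, Itga4 and Selplg, are named outside this rule. They were not followed in the alternative fits and are not in the counts of named genes.

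The alternatives were the replicate number as a blocking term, quantile normalization, centring each array on its median, dropping the genes below the median level, eBayes with trend and robust settings, array weights, an unmoderated linear model, the mean of all probes of a gene, and leaving out each array in turn. Leaving out both replicate 3 arrays was added after seeing the data. The same-numbered arrays of the 2 populations had correlations of their deviations from the group means of 0.0985, 0.0806 and 0.167. Not all were over 0.1, and the labels give no shared animal or day, so the main fit treated the arrays as sharing only a number. A shared origin of same-numbered arrays cannot be excluded, and the fit with the replicate number as a block allows for it. The scripts were tested on simulated data with the real genes' means and spreads for this comparison of 22180 genes. Of 67 genes changed by 1 on the log2 scale, 56.7% were recovered, against 80.6% of 67 changed by 2 and 93.9% of 66 changed by 4. With these 200 genes changed, limma made 7 false calls. With no gene changed, it made 0 calls. A list shifted by 1 was called with the preset correlation (adjusted p = 1.82e-24) and with the estimated one (adjusted p = 0.00902), and 0 other lists were called with the preset correlation. The simulated genes were drawn independently, so this does not show how the preset correlation does on real lists. The DNA replication list, which was the one shifted, had an estimated correlation of 0.264 in the real data.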

Results

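Expression profiles were obtained from 3 samples of YFP-positive and 3 samples of YFP-negative LSK cells of young mice in which Cdh5-driven Cre had been induced just after birth. The comparison addresses how LSK cells marked by endothelial Cre activity differ from unmarked LSK cells. Each array gave 41345 log2 values, of which 22180 genes with an unambiguous symbol were tested. Arrays of one population correlated at r = 0.946 to 0.968 across genes, and arrays of different populations at r = 0.888 to 0.924, where genes are not independent replicates. The mean distance was 0.101 between and 0.0439 within populations, a difference of 0.0575. The true split gave the largest difference of the 10 splits, with an exact one-sided permutation p = 0.1, the smallest this design allows. Xist, the RNA of the inactive X chromosome, stood at 10.3 ± 0.54 in YFP-positive and 10.3 ± 0.73 in YFP-negative arrays (SD, n = 3 each), and 0 of the 4 measured sex-linked genes passed limma's test (0 at an unadjusted p under 0.05, and 0 with the unmoderated model). Its level was highest in replicate 1 of both populations, at 10.9 in YFP-positive and 11.2 in YFP-negative cells, against 9.87 to 9.98 on the other arrays.

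The YFP-positive LSK samples had higher levels of a broad set of endothelial genes than the YFP-negative LSK samples. Their levels of some progenitor, lymphoid and DNA replication genes were lower. Whether endothelial cells were sorted among the YFP-positive cells is taken up below and stays open, so these levels cannot be assigned to blood cells. With limma, 1074 of 22180 genes (4.84%) passed an adjusted p of 0.05, 639 higher and 435 lower in YFP-positive cells. Among them, 314 genes were higher by at least 2 on the log2 scale and 75 were lower by as much. At 4 or more, 92 genes were higher and 4 lower. With the looser criterion, 2820 genes passed, 1280 higher and 1540 lower. At an unadjusted p under 0.05 there were 3820 genes, where chance gives 1109. For 16117 genes (72.7%) the 95% interval of the difference lay between -1 and 1. No filter on level was used, so these include genes near the lower end of the arrays. The share was smaller among genes above the median level, as given below. The count of genes past an adjusted p of 0.05 with limma was 559 and 607 without YFP-positive replicates 1 and 2, and 463, 430 and 611 without YFP-negative replicates 1, 2 and 3. It was 1185 without YFP-positive replicate 3. With the replicate number as a block it was 580 (412 higher, 168 lower), and with the unmoderated model 180 (145 higher, 35 lower).

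The driver gene of the lineage mark separated the populations. Cdh5 averaged 11.6 ± 0.28 in YFP-positive and 4.55 ± 0.85 in YFP-negative arrays (SD, n = 3 each), a difference of 7.03 ± 0.43 (SE) or 131-fold (adjusted p = 0.00086). Among genes that define or subdivide the LSK gate, Kit, the stem cell factor receptor, was 1.86-fold lower in YFP-positive cells (-0.89 ± 0.18, adjusted p = 0.0496). Cd34, a sialomucin of progenitors and of endothelium, was 4.89-fold lower (-2.29 ± 0.19, adjusted p = 0.00279). Cd48, carried by multipotent progenitors but not by most long-term stem cells, was 13.5-fold lower (adjusted p = 0.0209), and Flt3, the receptor of lymphoid-primed progenitors, 18.0-fold lower (adjusted p = 0.00507). Slamf1, which encodes CD150 of long-term stem cells, was low in both, at 3.21 ± 0.07 and 3.31 ± 0.17 (adjusted p = 0.796). Of the 14 gate genes measured, 1 rose, 5 fell and 8 did not pass, and adjusted over the list alone 3 rose and 5 fell. Ptprc, which encodes the leukocyte surface protein CD45, did not pass limma's test (adjusted p = 0.353), and its YFP-positive arrays differed widely. It measured 6.52, 6.95 and 9.52 in YFP-positive replicates 1, 2 and 3, against 9.23 to 9.37 in the YFP-negative arrays. Kit lost its call in each of the 6 fits that left out 1 array (highest adjusted p = 0.148). Cd48 lost it without YFP-positive replicate 2 and without each YFP-negative array (highest adjusted p = 0.0867).

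**Figure D1:**
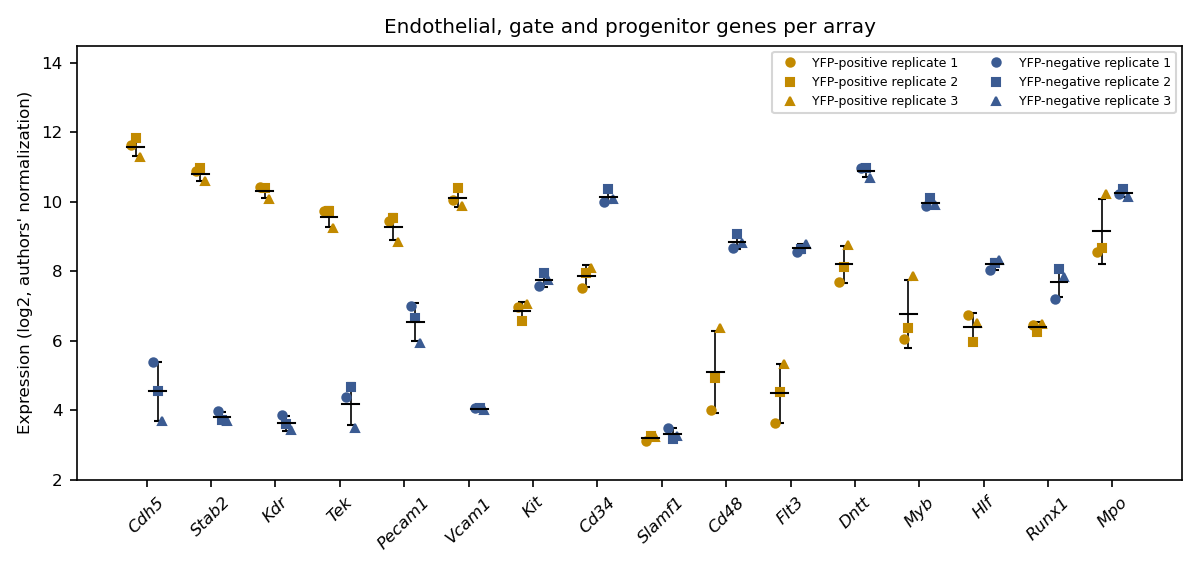
Log2 expression, as normalized by the authors, of endothelial genes (left), gate genes and progenitor genes (right) on each of the 6 arrays. Points are arrays, horizontal bars are means of 3 and error bars are SD. Cdh5 averages 11.6 in YFP-positive and 4.55 in YFP-negative arrays, and Flt3 averages 4.49 and 8.66.

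Of 31 measured endothelial genes, 25 rose in YFP-positive cells, 0 fell and 6 did not pass. Adjusted over the list alone, 27 rose. The median difference of the list was 3.21, and camera gave an adjusted p of 2.28e-37, against an adjusted p = 0.119 with an estimated correlation. Stab2, a scavenger receptor of sinusoidal endothelium, rose 130-fold (7.02 ± 0.15, adjusted p = 4.3e-05). Kdr, a receptor of vascular endothelial growth factor, rose 102-fold (6.67 ± 0.16), and Ptprb, the vascular endothelial protein tyrosine phosphatase, by 6.41 ± 0.12 on the log2 scale ( adjusted p = 3.87e-05). Flt4 rose 40.8-fold (5.35 ± 0.15, adjusted p = 5.75e-05), Tek 41.8-fold (5.39 ± 0.33) and Pecam1 6.71-fold (2.75 ± 0.32, adjusted p = 0.00956). Vwf, the von Willebrand factor of endothelium and platelets, measured 4.60 ± 0.26 against 4.06 ± 0.09 and did not pass (adjusted p = 0.143). Vwf passed without YFP-positive replicate 3 (adjusted p = 0.0431 to 0.328 over the 6 fits that left out 1 array).

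The 12 genes with the largest rise included Cdh5, Stab2, Kdr and Ptprb. Adamts5, a protease of the extracellular matrix, had the largest measured difference (7.26 ± 0.26, 153-fold, adjusted p = 0.000163). Mrc1, the mannose receptor of macrophages and sinusoidal endothelium, rose 109-fold. The 12 also held Pparg, a fatty acid-sensing nuclear receptor (101-fold, adjusted p = 0.000558), Cd36, a fatty acid transporter (100-fold, 6.64 ± 0.17), and Gpihbp1, which anchors lipoprotein lipase on capillary endothelium (90.1-fold). Epas1, a hypoxia-inducible factor, rose 89.2-fold, Ldb2, a transcriptional cofactor, 95.2-fold and the receptor Adgrf5 93.1-fold. In YFP-negative arrays these 12 genes averaged between 2.94 for Cd36 and 4.55 for Cdh5, against array medians of 3.62 to 3.68 over all probes. Levels below these medians, such as that of Adamts5 (3.17), cannot be told from background, so the sizes of these folds and the order of the 12 genes are not settled. All 12 kept their call in each of the 6 fits that left out 1 array (highest adjusted p = 0.00864).

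The 12 genes with the largest measured fall included Flt3 (-4.17 ± 0.41), Bex4 (17.7-fold lower, adjusted p = 0.00481), Angpt1, an angiopoietin made by blood stem and progenitor cells (15.9-fold), Cd48, Dapp1, a B lymphocyte adaptor (12.3-fold), Aff3, a lymphoid nuclear protein (11.3-fold, adjusted p = 0.0016), and Il12a, an interleukin subunit (-3.46). Bcl11a, a transcription factor needed for lymphoid development, was 9.66-fold lower, Cd27, a receptor of the tumour necrosis factor family, 9.28-fold, and Myb, a transcription factor of blood progenitors, 9.19-fold (-3.20 ± 0.47, adjusted p = 0.0194). Igkv4-72 and another variable segment of the immunoglobulin kappa locus were 18.0-fold and 15.2-fold lower, and these values are uncertain because near-identical segments can share probes. In YFP-positive arrays Bex4 averaged 2.93 and Igkv4-72 3.29, below the array medians, so the order of the 12 genes is not settled here either. Of the 12, 7 kept their call in each of the 6 fits that left out 1 array. Bcl11a lost its call without YFP-positive replicate 1 and YFP-negative replicates 1 and 2 (highest adjusted p = 0.0654), Cd27 without YFP-positive replicate 1 and each YFP-negative array (0.103), and Myb without each array but YFP-positive replicate 3 (0.0791). The other kappa segment lost it without each YFP-positive array and YFP-negative replicate 1 (0.0919).

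Of 19 lymphoid-primed progenitor genes, 5 fell, 0 rose and 14 did not pass, and 7 fell adjusted over the list alone (median -0.64, camera adjusted p = 0.000365, adjusted p = 0.191 with an estimated correlation). Dntt, the terminal transferase of early lymphoid cells, fell from 10.9 ± 0.16 to 8.20 ± 0.54 (6.44-fold, adjusted p = 0.00603). Il7r, a cytokine receptor of lymphoid progenitors, was 5.04-fold lower (adjusted p = 0.0026) and Satb1, a chromatin organiser of lymphoid cells, 2.67-fold lower (adjusted p = 0.00193). Beside this list, a list of 29 genes chosen as broadly expressed in leukocytes was written after the results were seen. These genes had a median of -1.56, with 4 lower past the threshold and 25 not (camera adjusted p = 0.229 with an estimated correlation). Their medians were -1.99, -1.93 and 0.12 in YFP-positive replicates 1, 2 and 3, against -0.73, -1.01 and -0.36 for the lymphoid-primed genes. Of 9 class II histocompatibility genes, 2 fell, H2-DMa (2.02-fold) and H2-Ob (1.60-fold), with a median of -0.63 and a camera adjusted p of 0.00387 (adjusted p = 0.191 with an estimated correlation). Adjusted over the list alone, the same number fell. H2-Ab1 and H2-DMb2 measured 3.65-fold and 9.17-fold lower and did not pass (adjusted p = 0.247 and 0.267). H2-DMa lost its call without YFP-positive replicates 1 and 2 and YFP-negative replicates 2 and 3 (highest adjusted p = 0.0741), and H2-Ob in all 6 such fits (0.121). H2-DMb2 passed without YFP-negative replicate 2 (0.00457 to 0.506 over the 6 fits).

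Blood stem cell genes moved in both directions. Of 26 long-term stem cell genes, 5 rose, 4 fell and 17 did not pass (camera adjusted p = 0.355), and adjusted over the list alone 9 rose and 5 fell. The list's median was -0.02 while its mean was 0.45. Those that rose were Ctnnal1 (10.7-fold, adjusted p = 0.000395), Tek, Sult1a1, Esam and Cdkn1c, of which Tek and Esam are also on the endothelial list. Those that fell were Meis1, Hlf, Adgrg1 and Mllt3. Hlf, a transcription factor of stem cells, was 3.48-fold lower (-1.80 ± 0.22, adjusted p = 0.0108), and lost its call without YFP-negative replicate 2 (adjusted p = 0.0515). Procr measured 4.52 ± 0.31 against 4.55 ± 0.32 (adjusted p = 0.97), Mecom 3.97 ± 0.61 against 5.01 ± 0.12 (adjusted p = 0.139) and Fgd5 5.52 ± 0.68 against 4.17 ± 0.35 (adjusted p = 0.118). None of the 3 passed.

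Of 20 transcription factors of haemogenic endothelium and blood stem cells, 5 fell, 1 rose and 14 did not pass (median -0.51, camera adjusted p = 0.0022, adjusted p = 0.248 with an estimated correlation). The numbers were the same adjusted over the list alone, and the leukocyte genes' median was -1.56. Runx1, needed for the emergence of blood from endothelium, fell from 7.70 ± 0.44 to 6.40 ± 0.13 (2.46-fold, adjusted p = 0.0359). Meis1 differed by -2.68 (adjusted p = 0.00672) and Etv6 was 2.52-fold lower (adjusted p = 0.0307), beside Bcl11a and Myb. Sox17, an endothelial and fetal stem cell factor, was the member that rose (1.65, adjusted p = 0.048). It was not followed in the fits that left out 1 array. Gfi1 measured 4.35 ± 0.04 against 4.54 ± 0.20 and did not pass (adjusted p = 0.581). Runx1 lost its call in 5 of the 6 fits that left out 1 array, all but the one without YFP-negative replicate 1 (highest adjusted p = 0.108). Etv6 lost it without YFP-positive replicate 1 and without each YFP-negative array (0.113). Of 15 fetal-type stem cell genes, 2 rose, Sox17 and Cdkn1c (2.18-fold), and Igf2bp3 fell (1.47-fold, camera adjusted p = 0.314 for the list). Of 17 Hox genes, Hoxa9 fell (2.91-fold, adjusted p = 0.00734) and Hoxb8 rose (1.95-fold, adjusted p = 0.0493, camera adjusted p = 0.319). Adjusted over the list alone, 3 rose and 2 fell in each of these 2 lists. Igf2bp3 lost its call in all 6 fits that left out an array, and Cdkn1c and Hoxb8 in all but the one without YFP-positive replicate 3 (highest adjusted p = 0.139, 0.109 and 0.151).

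Of 25 DNA replication genes, 8 fell, 0 rose and 17 did not pass, and 21 fell adjusted over the list alone (median -1.29, camera adjusted p = 2.64e-12, adjusted p = 0.191 with an estimated correlation). Beside them, the leukocyte genes had a median of -1.56 and the endothelial genes of 3.21. Mcm6, a subunit of the replicative helicase, was 4.50-fold lower (adjusted p = 0.0252). Gins2 was 3.35-fold, Cdc45 3.32-fold and Pola1, the catalytic subunit of polymerase alpha, 2.74-fold lower. All 24 measured G2 and M phase genes had a difference below 0, of which 2 passed, Prc1 (3.13-fold) and Cenpf (2.07-fold), and 7 fell adjusted over the list alone (median -0.84, camera adjusted p = 8.6e-07, adjusted p = 0.417 with an estimated correlation). Mki67, Cdk1 and Kif11 measured 1.94-fold, 2.76-fold and 3.51-fold lower and did not pass (adjusted p = 0.38, 0.0549 and 0.0748). YFP-positive replicate 3 stood apart here. Its G2 and M phase median was -0.05 against the YFP-negative mean, where replicates 1 and 2 had -1.14 and -1.38, and its neutrophil median was 2.54. Without it Mki67 (adjusted p = 0.0195 to 0.65 over the 6 fits that left out 1 array) and Kif11 (0.00909 to 0.213) passed, and without YFP-negative replicate 1 Cdk1 did (0.0356 to 0.154). Each of Mcm6, Gins2, Cdc45, Pola1, Prc1 and Cenpf lost its call in 2 to 5 of the 6 fits that left out an array (highest adjusted p = 0.146, for Cenpf).

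Of 31 cytosolic ribosomal protein genes, 9 fell, 1 rose and 21 did not pass, and adjusted over the list alone 17 fell and 1 rose (median -0.40, camera adjusted p = 2.18e-07, adjusted p = 0.191 with an estimated correlation). The leukocyte genes' median was -1.56 and the endothelial genes' 3.21 in the same comparison. Rps4x was 1.68-fold and Rpl27 and Rplp1 each 1.82-fold lower. Rpl3 was the member that rose on its brightest probe (1.48 ± 0.13), but its difference was -0.21 as the mean of its probes. Of 29 oxidative phosphorylation genes, 3 fell, Ndufv2 (2.18-fold), Atp5a1 (1.63-fold) and Atp5c1 (1.58-fold), and 8 fell adjusted over the list alone (median -0.45, camera adjusted p = 8.6e-07, adjusted p = 0.119 with an estimated correlation). Cox5a measured 1.58-fold lower and did not pass (adjusted p = 0.0524). Besides Rpl3, which kept its call, the genes named here that fell lost theirs in 3 to 6 of the 6 fits that left out an array (highest adjusted p = 0.13, for Ndufv2). Of 17 glycolysis genes, 0 passed limma's test (4 at an unadjusted p under 0.05, 0 with the unmoderated model), and 2 fell adjusted over the list alone. Pgk1 and Hk1 had the smallest p (adjusted p = 0.0587 and 0.08), and Pgk1 passed without YFP-positive replicate 3 (0.0153 to 0.177 over the 6 fits that left out 1 array). Camera gave an adjusted p of 0.319 for the list, and 0.0257 without YFP-positive replicate 3.

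**Figure D2:**
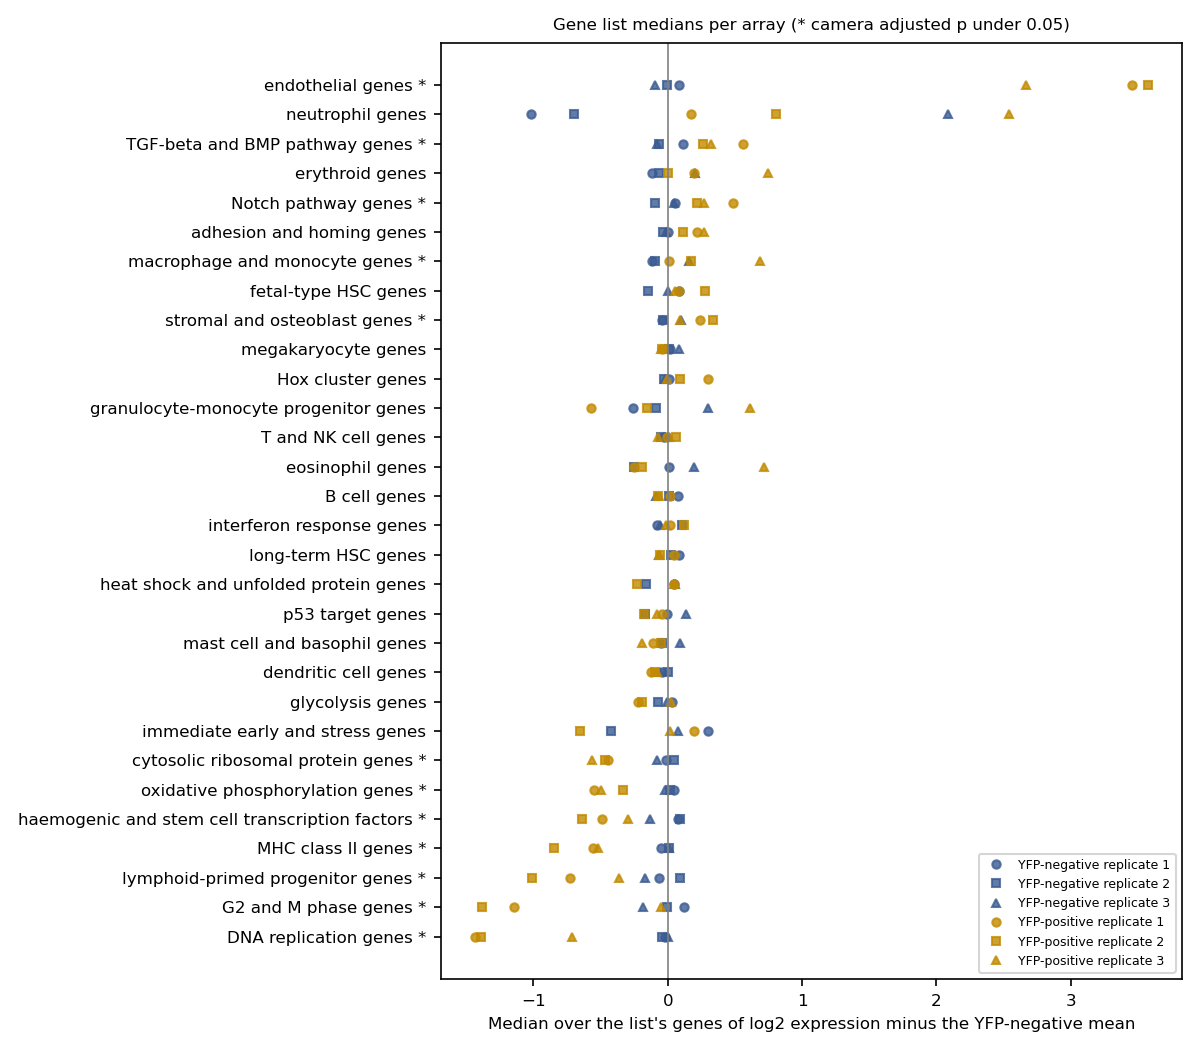
Median over each gene list of log2 expression minus the mean of the YFP-negative arrays, for the 30 tested lists (rows, ordered by the median difference) on each of the 6 arrays (points). Asterisks mark lists past camera's adjusted p of 0.05 with the preset correlation. The endothelial list stands at 2.67 to 3.58 in the YFP-positive arrays, and the neutrophil list is highest in replicate 3 of both populations, at 2.54 and 2.09.

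Of 22 genes of the TGF-beta and BMP pathways, 5 rose and 1 fell, and adjusted over the list alone 8 rose and 1 fell (median 0.46, camera adjusted p = 0.000365, adjusted p = 0.174 with an estimated correlation). The endothelial list's median was 3.21, with 25 of 31 genes higher past the threshold. Eng, an endothelial co-receptor of TGF-beta, rose 10.2-fold (3.35 ± 0.21, adjusted p = 0.00101), Id3, a target of BMP signalling, 12.3-fold (adjusted p = 0.01) and Acvrl1, an endothelial receptor, 2.63-fold. Tgif1, a repressor of the pathway, was 1.95-fold lower. Of 22 Notch pathway genes, 2 rose, Hey1 (2.70-fold) and Notch4 (1.80-fold), and 6 rose adjusted over the list alone (median 0.29, camera adjusted p = 0.000891, adjusted p = 0.191 with an estimated correlation). Hey1 and Jag1 are also genes of arterial endothelium. Jag1 and Lfng measured 5.83-fold and 1.69-fold higher and did not pass (adjusted p = 0.0562 and 0.0712), and Jag1 passed without YFP-positive replicate 3 (0.00253 to 0.168 over the 6 fits that left out 1 array). Of 21 adhesion and homing genes, 6 rose and 3 fell, 7 and 4 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.13, and 0.0493 without YFP-positive replicate 1). Vcam1 rose 67.2-fold (6.07 ± 0.15) and S1pr1, the sphingosine-1-phosphate receptor, 6.67-fold, while the progenitor integrin Itga4 (-1.94) and the selectin ligand Selplg (-2.20) fell. Acvrl1, Tgif1, Hey1 and Notch4 lost their calls in 3 or 4 of the 6 fits that left out an array (highest adjusted p = 0.0806, 0.0703, 0.0774 and 0.0763).

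Markers of other cell types gave a mixed picture. Of 18 neutrophil genes, 0 passed limma's test (1 at an unadjusted p under 0.05, 0 with the unmoderated model). Their median difference was 1.07, and the list did not pass camera (adjusted p = 0.0751). It passed without YFP-positive replicate 1 (adjusted p = 0.00773), without YFP-positive replicate 2 (0.043), without YFP-negative replicate 3 (9.76e-07) and with the replicate number as a block (1.78e-06). These values use the preset correlation. The estimated correlation of this list was 0.865, and with it camera's adjusted p in the main fit was 0.771. Neutrophil genes were high on replicate 3 of both populations. Ngp, a granule protein, differed by 1.61 ± 0.91 (SE, adjusted p = 0.463), and Padi4 measured 4.02 ± 0.37 against 4.82 ± 0.40 (adjusted p = 0.198). Of the 18 genes, 17 had a difference above 0, and Padi4 was the exception. Of 20 macrophage and monocyte genes, 3 rose (4 adjusted over the list alone, median 0.27, camera adjusted p = 0.000891, adjusted p = 0.191 with an estimated correlation). They were Mrc1 and Vcam1, which sinusoidal endothelium also expresses, and Mertk (3.34-fold, adjusted p = 0.046), which lost its call in 4 of the 6 fits that left out an array (highest adjusted p = 0.141). Hmox1 measured 6.53-fold higher (adjusted p = 0.077), and passed without YFP-negative replicate 2 (0.0431 to 0.211 over the 6 fits). Of 20 stromal and osteoblast genes, 2 rose, Sparc (67.7-fold) and Lpl (19.4-fold), both of which endothelium can express, and 6 rose adjusted over the list alone (median 0.17, camera adjusted p = 0.00574, adjusted p = 0.273 with an estimated correlation). Adipoq and Col5a2 did not pass (adjusted p = 0.0658 and 0.079).

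The other lists of blood lineages did not pass camera. In the granulocyte-monocyte progenitor list, 0 of 18 genes passed limma's test (4 at an unadjusted p under 0.05, 0 with the unmoderated model), with a median of 0.06, a mean of -0.09 and an adjusted p of 0.676 for the list. Mpo, the myeloperoxidase of granulocyte progenitors, measured 9.15 ± 0.94 against 10.2 ± 0.12 (adjusted p = 0.293), Nkg7 4.59-fold lower (adjusted p = 0.109) and Prtn3 1.53-fold lower (adjusted p = 0.155). Without YFP-positive replicate 3, the list passed with the preset correlation (adjusted p = 0.0223) and so did Mpo (0.00483) and Nkg7 (0.0168). With an estimated correlation, camera's adjusted p for the list in the main fit was 0.986. Of 15 megakaryocyte genes, Selp, P-selectin of platelets and endothelium, rose (8.14-fold, adjusted p = 0.00734, list adjusted p = 0.982). Of 12 erythroid genes, 0 passed limma's test (2 at an unadjusted p under 0.05, 0 with the unmoderated model, list adjusted p = 0.317), and 1 rose and 1 fell adjusted over the list alone. Epor and Car2 had adjusted p of 0.0517 and 0.0616, and passed without YFP-positive replicates 2 (0.0157 to 0.16) and 3 (0.0346 to 0.185), respectively. Of 15 B cell genes, Cd79b, a chain of the B cell receptor complex, fell (3.99-fold, adjusted p = 0.0031, list adjusted p = 0.395). Ighm measured 6.99-fold lower (adjusted p = 0.128), and passed without YFP-positive replicate 2 (0.00888 to 0.304). Of 16 dendritic cell genes, Flt3 fell and Cd209a rose (1.75-fold, adjusted p = 0.0479, list adjusted p = 0.427), and Cd209a lost its call in all 6 fits that left out an array (highest adjusted p = 0.145). Adjusted over the list alone, 1 megakaryocyte gene rose, 1 B cell gene fell, and 3 dendritic cell genes rose and 2 fell.

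In 3 more lineage lists, limma called 0 genes, also over the list alone and with the unmoderated model. Of 18 T and NK cell genes, 3 had an unadjusted p under 0.05, with a median of 0.02, a mean of -0.26 and a list adjusted p of 0.965. Lat measured 3.51-fold lower (adjusted p = 0.164). Of 14 mast cell and basophil genes, 0 had an unadjusted p under 0.05 (list adjusted p = 0.317), and Mcpt8 and Cma1 had adjusted p of 0.345 and 0.445. Of 8 eosinophil genes, 1 had an unadjusted p under 0.05 (list adjusted p = 0.982), and Siglecf and Prg3 had adjusted p of 0.217 and 0.716.

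The lists of stress programs did not pass camera. Of 28 immediate early and stress genes, 1 rose, Socs3, a feedback inhibitor of cytokine signalling (3.45-fold, adjusted p = 0.0285, list adjusted p = 0.786). Junb measured 1.85-fold higher (adjusted p = 0.165). Of 19 p53 target genes, 1 rose, Plk2 (2.51-fold, adjusted p = 0.0474, list adjusted p = 0.558), and Trp53inp1 had an adjusted p of 0.238. The counts of both lists were the same adjusted over the list alone. Socs3 and Plk2 lost their calls in 4 and 5 of the 6 fits that left out an array (highest adjusted p = 0.105 and 0.149). Of 25 interferon response genes, limma called 0 (5 at an unadjusted p under 0.05, 0 with the unmoderated model, 0 adjusted over the list alone). The list adjusted p was 0.965, with a median of -0.02 and a mean of 0.01, and Dhx58 and Oas3 had adjusted p of 0.152 and 0.173. Of 20 heat shock and unfolded protein genes, limma called 0 (4 at an unadjusted p under 0.05, 0 with the unmoderated model, 0 adjusted over the list alone). The list adjusted p was 0.982 with camera's direction upward and a median of -0.03. Xbp1 and Hspe1 had adjusted p of 0.0608 and 0.112, and Xbp1 passed without YFP-positive replicate 3 (0.0103 to 0.182).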

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

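Of the tests below, those on single arrays or replicates, on the stromal list and on neutrophil genes were chosen after the result was seen, and so were the requirements that each array meet the bound on leukocyte genes and that the dilution test clear its bound with its interval and with paired genes. The leukocyte list and the other bounds on it were written after the main comparison was seen and before the leukocyte medians were. Probes outside the comparison also separated the populations. Among 16010 probes with no gene listed, 40 passed limma's adjusted p of 0.05, 27 higher and 13 lower, with differences up to 8.10. Among 1814 probes with several gene symbols, 34 passed, 10 higher and 24 lower, down to -7.31. No test of single outlying samples was run on these groups of 3 arrays.

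The first pattern is the endothelial profile of the YFP-positive arrays. A lower share of blood cells that raised the markers of every other cell type alike would raise the stromal list as much. The median of the endothelial list exceeded that of the stromal list by 3.03 (95% bootstrap interval over genes 1.76 to 4.94). A comparison with the neutrophil list was made first and gave 2.14 (0.99 to 4.15), which just missed the bound of 1 for the interval, and the stromal list replaced it because neutrophils are themselves blood cells. That choice came after the result was seen, and the interval covers genes but not arrays, so it cannot exclude this explanation. In the YFP-positive arrays the endothelial list stood at 2.67 to 3.58 and the stromal list at 0.09 to 0.33. If endothelial cells had been sorted among the YFP-positive cells, the 29 leukocyte genes should be lower. Over all 3 arrays their median was -1.56 (interval -1.79 to -0.88). This met the bound first written for that explanation and against LSK cells with an unreduced blood program that also carry endothelial transcripts. That bound left out the spread between arrays, with medians of -2.01 (-2.55 to -1.38) in replicates 1 and 2 and 0.12 (-0.32 to 0.21) in replicate 3, so each array was then required to meet it. Replicates 1 and 2 were set apart by these same medians, so their value is no independent test of either explanation. It cannot support endothelial cells in the sorted fraction. In these 2 arrays leukocyte genes did stand below the YFP-negative arrays, which an unreduced blood program would not give. Since neutrophil signal may raise leukocyte genes in replicate 3, both explanations stay open there and over the 3 arrays. Cells in transition with both programs stay open in all arrays.

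The second pattern is that YFP-positive replicate 3 lay nearer to the YFP-negative arrays, at r = 0.911 to 0.924 against 0.888 to 0.892 for replicates 1 and 2. A higher share of blood cells in that array may account for it. Set gene by gene against the mean of replicates 1 and 2, the median deviation in replicate 3 was 1.99 for leukocyte genes and -0.47 for endothelial genes. Neutrophil-lineage cells in both replicate 3 samples are a candidate source, with a median deviation of neutrophil genes of 1.88 in YFP-positive and 3.13 in YFP-negative cells (interval of the second 1.79 to 3.66). In YFP-positive replicate 3, medians against the YFP-negative mean were also raised for granulocyte-monocyte progenitor (0.61), erythroid (0.75), macrophage (0.69) and eosinophil genes (0.72). In YFP-negative replicate 3 these were 0.30, 0.20, 0.16 and 0.19. Megakaryocyte, B cell, T and NK cell, mast cell and dendritic cell medians lay between -0.19 and -0.05 in YFP-positive replicate 3. Sources other than neutrophils were not tested. The lineage gate should remove mature neutrophils, and S100a8 and S100a9 stood at 10.5 or more on all 6 arrays.

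The third pattern is the lower level of DNA replication genes. Their median lay 0.27 above that of the leukocyte genes (interval -0.52 to 0.87), which met the bound first written for dilution of the blood cells by others but not the stricter one, so dilution could account for it but is not shown. In YFP-positive replicate 3 the replication median was -0.71 and the leukocyte median 0.12, which decides nothing, because neutrophils may raise leukocyte genes there. Against leukocyte genes paired on the nearest YFP-negative level, to allow for compressed folds of bright probes, the median difference was -0.64 (interval -1.07 to -0.09, with 13 distinct partners for 25 genes). Dilution, probe brightness and a lower proliferation of the YFP-positive blood cells all stay open, and the last was not tested.

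The count of 1074 genes was set against all 10 splits of the arrays into 3 and 3. The true split was the only 1 with as many, and the highest other split called 0 genes with limma (938 at an unadjusted p under 0.05, and at most 1 gene with the unmoderated model, against 3820 at that p in the true split). With 10 splits, no share under 0.05 can be reached. Each other split mixes the populations, so the difference between them enters the spread within its groups. A low count in those splits was therefore built in, and it does not measure what chance alone would give.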

How the results depend on the processing

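The cause of the changes below was not tested. The count of 1074 genes stayed between 800 and 1210 under quantile normalization, median centring, the level filter, the trend and robust fit, array weights, the mean of probes and without both replicate 3 arrays, was 180 with the unmoderated linear model (145 higher, 35 lower, 169 of them among the 1074), and ranged from 430 to 1185 without single arrays. With the replicate number as a block it was 580, of which 514 were among the 1074. Each YFP-positive array correlated best with the YFP-negative array of its own number (0.0985, 0.0806 and 0.167), a hint from the data only. Xist was also highest in replicate 1, and neutrophil genes in replicate 3, of both populations, so pairing by number cannot be excluded. The share of higher calls was 59.5%, but 71.0% under the block and 80.6% with the unmoderated model. The looser count stayed between 2082 and 3177. The count of genes with an interval between -1 and 1 was 5380 of 11090 under the level filter and between 14788 and 16265 elsewhere. Of the 72 named genes past the threshold, 38 kept their call in each of the 6 fits without 1 array, and 28, 23 and 9 lost it without YFP-positive replicates 1, 2 and 3, and 28, 32 and 25 without YFP-negative replicates 1, 2 and 3. The block ended 27 of the 72 calls, the unmoderated model 46, the trend and robust fit 12, quantile normalization 6 and median centring 3. The rise of Rpl3 turned to -0.21 as the mean of its probes, and no other of the 72 reversed.

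With an estimated correlation, camera called 0 of 30 lists (7 at an unadjusted p under 0.05) in place of 12, and fry called 14, of which 11 were among the 12. The adjusted p with an estimated correlation was 0.119 for endothelial and oxidative phosphorylation genes, 0.174 for TGF-beta and BMP genes, 0.191 for lymphoid-primed, Notch, DNA replication, ribosomal, class II and macrophage genes, 0.248 for haemogenic transcription factors, 0.273 for stromal genes and 0.417 for G2 and M phase genes. The same 12 lists passed in each fit without 1 array, and under the replicate block. Fry lost G2 and M phase genes (0.115) and added long-term stem cell (0.0251), adhesion (0.00395) and dendritic cell genes (0.019). It tests a list against no change and not against the other genes, so its calls answer another question than camera's. Class II genes reached 0.0584 with the level filter, which left 5 of them. With the preset correlation, neutrophil genes passed camera under the replicate block (1.78e-06), median centring (0.0461) and without both replicate 3 arrays (3.66e-06), and ranged from 9.76e-07 to 0.727 without single arrays. With an estimated correlation their adjusted p in the main fit was 0.771. The ranges without single arrays, also with the preset correlation, were 0.0493 to 0.64 for adhesion, 0.0223 to 0.992 for granulocyte-monocyte progenitor and 0.0257 to 0.567 for glycolysis genes. The difference of distances between and within populations, 0.0575, was 0.134 with the level filter, 0.665 over the genes of largest variance, 0.0315 with Spearman correlation, 1.34 after removing replicate means, 0.0737 without both replicate 3 arrays and 0.0534 to 0.0704 without single arrays. Removing replicate means turns same-numbered arrays into mirror images, so 1.34 is inflated by the arithmetic. The genes of largest variance were picked on these same arrays, which inflates 0.665. Neither value adds support. The planned change of pseudocount was not run because the values were already log2. The smallest array set, 2 against 2, and levels near the lower end of the arrays limit what these data can show.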

Other observations

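The lists and tests in this part were chosen after the result was seen. Of 15 genes of sinusoidal endothelium, 12 rose, with a median of 5.35 (camera adjusted p = 8.75e-26 over 4 lists made later, adjusted p = 0.0157 with an estimated correlation). Besides Stab2, they included Gpr182 (6.38), Maf (6.28), Plvap (5.19) and F8, coagulation factor VIII (5.61). Lyve1 and Clec4g, of lymphatic and liver endothelium, measured -0.01 and -0.02. Clec4g averaged 2.81 in YFP-positive and 2.83 in YFP-negative arrays, below the array medians, so its levels cannot be told from background. Of 17 genes of arterial endothelium, 4 rose, with a median of 0.67 (adjusted p = 2.24e-05, 0.121 with an estimated correlation). They were Nrp1 (4.47, adjusted p = 0.00806), Sox17 (1.65), Hey1 (1.43) and Fbln5 (0.67). Tm4sf1 measured 2.84 and did not pass (adjusted p = 0.0748), and Gja4 and Gja5, gap junction proteins of arteries, measured -0.09 and 0.08. In YFP-positive and YFP-negative arrays Gja4 averaged 3.07 and 3.17, below the array medians, and Gja5 3.81 and 3.73, just above them. At such levels a difference near 0 does not show unchanged expression. The sinusoidal median exceeded the arterial by 4.68 (95% bootstrap interval over genes 3.36 to 5.99). The sinusoidal list was written with some of its genes, such as Adamts5, Stab2 and Mrc1, already seen at the top, and 5 of its members were on the endothelial list, so the difference shows nothing about the type of endothelium, which stays open.

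Of 17 genes of fatty acid handling, 9 rose and 1 fell, with a median of 1.57. The list was written after Pparg, Cd36 and Gpihbp1 had been seen among the largest rises and holds them, so no test of it is independent. Those that rose included Pparg, Cd36 and Gpihbp1, the fatty acid-binding protein Fabp4 (5.11), the lipases Lpl (4.28) and Lipg (5.71), Angptl4 (3.72) and Plin2 (1.78), while Fabp5 fell (-1.07). The fatty acid transporters Slc27a1 and Slc27a3 measured 0.00 and -0.06. Slc27a3 averaged 3.50 in YFP-positive and 3.56 in YFP-negative arrays, below the array medians, so its levels cannot be told from background. Of the macrophage genes, C1qa measured 0.04 and Adgre1 -0.03, beside the rise of Mrc1 and Vcam1. Of the 29 leukocyte genes, 26 had a difference below 0 and 4 passed (camera adjusted p = 3.94e-08, 0.229 with an estimated correlation). The 4 were Vav1 (-2.56), Btk (-1.76), Fermt3 (-1.63) and Inpp5d (-1.56).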
